A study of Homo sapiens with 6 samples.

How the data were processed

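RNA was measured by sequencing in 6 libraries of SW480, an established human colorectal cancer cell line, 3 after transfection with a negative control siRNA and 3 after transfection with an siRNA against ITGB4. The series describes the 3 libraries of a group as biological replicates. Per the labels, messenger RNA was captured from total RNA on poly-T beads. The labels give no siRNA sequence, time after transfection, read length or strandedness, and they name no second siRNA against ITGB4. Reads from overlapping genes on opposite strands therefore cannot be assigned from the labels.

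The deposited table holds FPKM (fragments per kilobase of gene length, scaled to a library size), computed by the authors for 58735 genes of the GRCh38 build, with the gene length in bases that the authors used. The submitters' processing notes name DESeq2 and edgeR without saying what each was used for, and name no aligner or counting tool. A mean FPKM per group is also deposited by the authors, and it equals the mean of the 3 libraries within 6.7e-07 FPKM. Multiplied by gene length and divided by the value of 1 read, 100% of the values of each library were whole numbers at a tolerance of 0.01, so the reads per gene could be recovered. These gave 14793429, 14833293 and 15186046 reads for control siRNA replicates 1, 2 and 3 and 13715266, 15256686 and 15496274 for ITGB4 siRNA replicates 1, 2 and 3. Counting error is therefore small for abundant genes, and the spread between replicates sets the precision of the comparisons. The library size implied by the authors' FPKM was 0.9991 to 1.01 times the recovered reads, so it was not the plain read total. How it was set is not stated.

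Groups were taken from the sample titles. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 12871 in all, of which 10592 are annotated as protein coding. The log2 of FPKM + 1 was fitted with limma 3.58.1 in R 4.3.3, with a moderated variance that follows the mean (limma-trend), 1 coefficient for the siRNA and no replicate term. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. Single genes were also compared by an exact two-sided permutation test of the mean FPKM, which with 3 against 3 libraries cannot give a p under 0.1. Intervals are 95% confidence intervals.

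Before the data were examined, 32 gene lists were written from general knowledge, with 941 members, of which 931 matched a symbol in the table. The 28 lists with at least 5 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. The rule for named genes was fixed before the data were examined as well. It took ITGB4, EZR and CTNNB1 whatever their values. It also took up to 12 protein-coding genes in each direction with an adjusted p under 0.05, no overlap between the groups and a mean FPKM of at least 5 in the higher group, and up to 4 members per described list with the smallest adjusted p. Genes named outside this rule are marked as such.

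The tests were checked on simulated data with the means and spread of these libraries. In 10 simulations limma-trend found 10.4% of genes changed 1.25-fold, 45.6% of those changed 1.5-fold, 77.6% at 2-fold and 91.2% at 4-fold, and 6.3% of its calls were false. Each simulation held many more changed genes than the 6 that limma called in the real data. With more changed genes the adjusted threshold is easier to pass, so these rates can overstate the power for single genes here. Camera found a list of 30 genes shifted by -0.2 (log2) in 10 of 10 simulations and a list with no shift in 0 of 10. The simulated genes were drawn independently of each other, and each list was judged at an unadjusted p under 0.05. The planted shift was also larger than the list medians of these data (-0.071 to 0.04). The check therefore does not give the error rate or the power for the lists reported here.

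After the data had been seen, limma-voom was run on the recovered reads, and a scan of 7-base words in 3′ UTRs was added. The scan used the longest 3′ UTR annotated in GENCODE for 10474 protein-coding genes, with at least 50 genes per word. It ranked log2 fold changes after regressing out UTR length and GC content, and adjusted over 16178 words by the Bonferroni method. With the fold changes shuffled over genes, a word shifted by -0.15 or -0.05 (log2) ranked 1, and 0 words passed with no shift. This was a single shuffle per shift, counted words for lower genes only, and removed the correlation between genes. In other splits of the 6 libraries, tested in both directions, 0 to 23 words passed. The check therefore does not show that the Bonferroni-adjusted p-values of the scan are calibrated. It ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots were drawn with matplotlib 3.10.9.

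The alternatives tried were another pseudocount, no filter and a stricter filter on low values, rescaling of the libraries, robust moderation, library weights, the replicate number as a block, and leaving out each library in turn. The planned tests on counts with edgeR and DESeq2 were not run, and limma-voom was run on the recovered reads in their place. No library was left out of the main comparison. Lists with fewer than 5 tested members (intestinal differentiation, fibroblast, endothelium and leukocyte) were described by their levels only.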

Results

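The data are gene expression values for 6 libraries of SW480 colorectal cancer cells, 3 with a negative control siRNA and 3 with an siRNA against ITGB4. The libraries held 13715266 to 15496274 recovered reads, and 24284 to 24968 genes had a value above 0. Mitochondrially encoded genes took 4.70% to 5.49% of the reads and the 10 most abundant genes 5.52% to 6.12%, with overlapping ranges in both groups. Of the marker genes of other cell types, FBLN1 (fibroblasts) averaged 1.15 FPKM, ESAM (endothelium) 1.002 and CD74 (leukocytes) 2.21, and the other markers of these lists had means under 1 FPKM over the 6 libraries. The first principal component took 27.8% of the variance and did not part the groups. It was negative in replicate 1 of both groups (-17.27 with control siRNA, -10.8 with ITGB4 siRNA) and positive in the other libraries (3.28 to 14.36). The second took 21.4% and was negative in 3 of 3 control libraries and positive in 3 of 3 ITGB4 siRNA libraries. The comparison asks which transcripts differ when ITGB4 is depleted, and the series title names Ezrin and the Wnt/β-catenin pathway.

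ITGB4, the integrin β4 subunit that pairs with α6 in hemidesmosomes, fell by 43.7% with its siRNA. It went from 69.3 ± 5.26 FPKM (SD, n = 3) to 39.0 ± 1.80 (SD, n = 3). EI24, an endoplasmic reticulum membrane protein, fell by 46.4%, from 40.0 ± 2.32 to 21.4 ± 0.971 FPKM, and TPRG1L fell by 41.5%, from 26.3 ± 0.888 to 15.4 ± 0.916 FPKM (SD, n = 3 each). TPM4, an actin-binding tropomyosin, rose by 57.2%, from 45.4 ± 2.36 to 71.4 ± 1.53 FPKM, and GANAB, the catalytic subunit of the glucosidase II of the endoplasmic reticulum, rose by 40.2%, from 92.6 ± 1.82 to 129.8 ± 1.90 FPKM (SD, n = 3 each). In each of these 5 genes the values of the groups did not overlap. In their 3′ UTR, EI24 and TPRG1L carry the words ATTGGAT and TTGGATA and TPM4 carries TCGGAGA and CGGAGAA. GANAB and ITGB4 carry none of these 4 words there.

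ITGB4 (ENSG00000132470; GRCh38 chromosome 17, 75721328 to 75757818, plus strand) had a log2 fold change of -0.81 (SE 0.0658, 95% interval -0.97 to -0.66, limma adjusted p = 0.0148). EI24 (ENSG00000149547; chromosome 11, 125569216 to 125584687) changed by -0.87 (SE 0.0585) and TPRG1L (ENSG00000158109; chromosome 1, 3625002 to 3630127) by -0.74 (SE 0.0565). TPM4 (ENSG00000167460; chromosome 19, 16067021 to 16103005) changed by 0.64 (SE 0.0495) and GANAB (ENSG00000089597; chromosome 11, 62624826 to 62646726) by 0.48 (SE 0.0368). Each of these 4 had a limma adjusted p of 0.0137. The exact permutation test of each of these 5 genes gave p = 0.1, the smallest that 3 against 3 libraries allow. A 6th called gene, AC012531.4, is a 151-base RNA of the class misc_RNA on chromosome 12 (53968351 to 53968501). It had 1 read in each control library and 8, 6 and 7 reads in the ITGB4 siRNA libraries, for a log2 fold change of 1.51 (limma adjusted p = 0.0148). At so few reads its size depends on the pseudocount, and it was 2.56 with a pseudocount of 0.1 and 2.24 as TPM. With limma-voom on the recovered reads it was 2.32 with an adjusted p of 0.357, and the gene was chosen for naming after its values were seen.

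Of 12871 genes tested, limma called 6 changed, 3 higher and 3 lower, of which AC012531.4 alone differed at least 2-fold. At an unadjusted p under 0.05 there were 750 genes, where chance gives 644, and 1430 genes (11.1%) had groups that did not overlap, where chance gives 10%. Limma-voom, chosen after seeing the data, called 26 genes, 12 higher and 14 lower, and 5 genes (ITGB4, EI24, TPRG1L, TPM4 and GANAB) were called by both. Without ITGB4 siRNA replicate 1, 2 or 3, limma called 0 genes (607, 544 and 581 at an unadjusted p under 0.05; limma-voom was not rerun), and without control siRNA replicate 3 it called 3, of which EI24 alone was among the 6. Without the filter on low values it called 0 of 31956 genes (1356 at an unadjusted p under 0.05), with ITGB4 at an adjusted p of 0.0618.

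**Figure D1:**
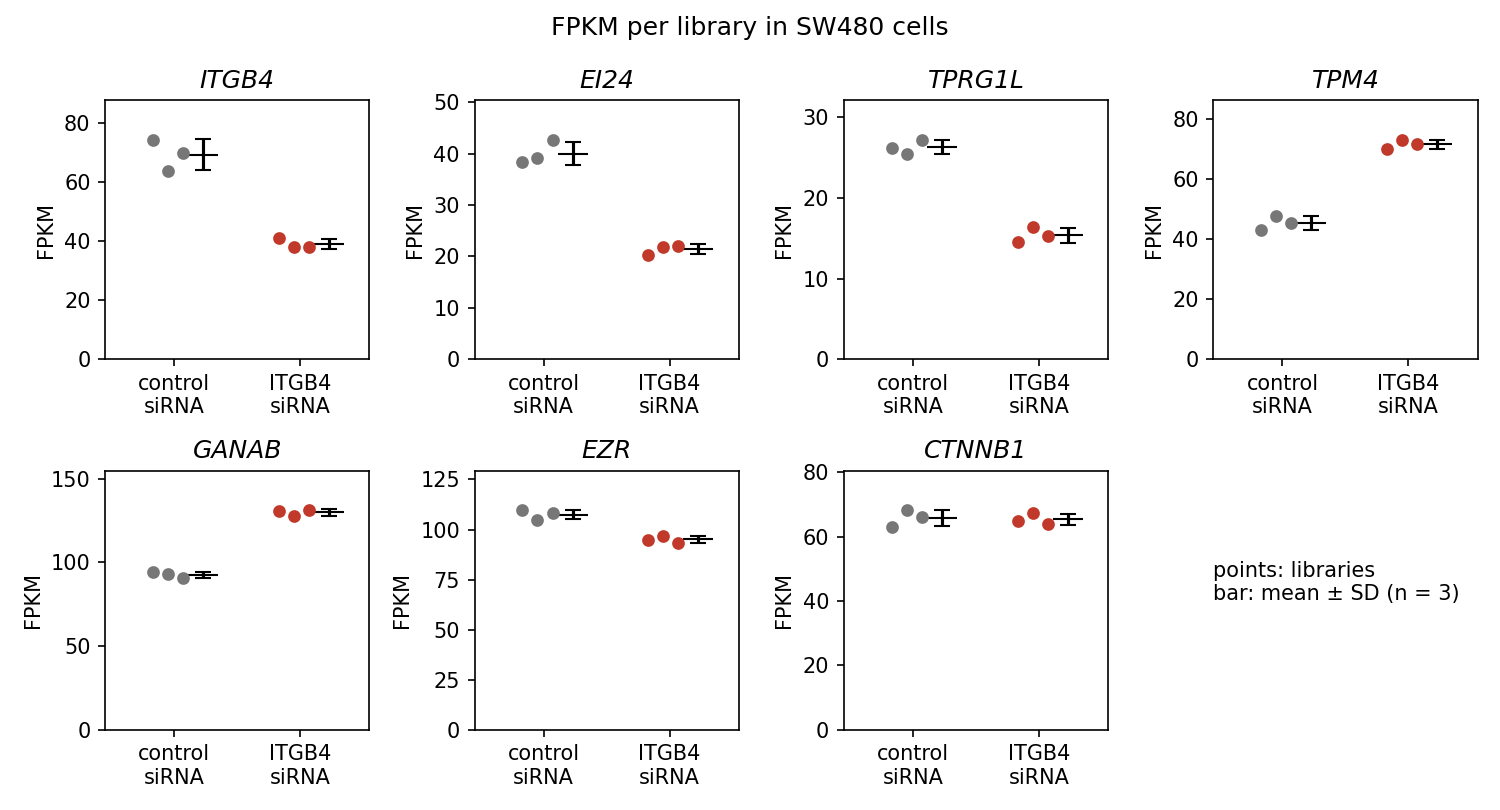
FPKM of ITGB4, EI24, TPRG1L, TPM4, GANAB, EZR and CTNNB1 in each of the 6 libraries, with 1 point per library and bars for the mean ± SD of the 3 libraries of a group. ITGB4 lies at 63.8 to 74.3 FPKM with control siRNA and at 37.9 to 41.1 with ITGB4 siRNA, while the values of CTNNB1 overlap.

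EZR encodes ezrin, which links actin filaments to the plasma membrane. It was measured at 107.5 ± 2.44 FPKM (SD, n = 3) with control siRNA and at 95.03 ± 1.59 (SD, n = 3) with ITGB4 siRNA, a difference of -11.6%. All 3 ITGB4 siRNA libraries lay below all 3 control libraries. CTNNB1, the gene of β-catenin, was measured at 65.8 ± 2.53 and 65.4 ± 1.72 FPKM (SD, n = 3 each). EZR (ENSG00000092820; GRCh38 chromosome 6, 158765741 to 158819412, minus strand) had a log2 fold change of -0.18 (SE 0.038, 95% interval -0.27 to -0.09), which did not pass over all genes (limma adjusted p = 0.451; limma-voom 0.317). It passed when adjusted over the list alone, that of ezrin, radixin, moesin and their partners (limma adjusted p = 0.0446), and its exact permutation p was 0.1. CTNNB1 (ENSG00000168036; chromosome 3, 41194741 to 41260096, plus strand) had a log2 fold change of -0.01 (95% interval -0.12 to 0.10, limma adjusted p = 0.998), and its sign turned without control siRNA replicate 2 (0.02) or without ITGB4 siRNA replicate 3 (0.01).

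Among 29 tested Wnt/β-catenin target genes, 19 had a log2 fold change below 0 and 10 above it, with a median of -0.03. Limma called 0 of them changed over all genes tested (5 lower and 1 higher at an unadjusted p under 0.05; limma-voom 0), and 1, ID2, passed when adjusted over the list alone. ID2, an inhibitor of helix-loop-helix transcription factors, was at 106.7 ± 4.43 and 90.5 ± 2.87 FPKM (log2 fold change -0.24), and CCND1, cyclin D1, was at 544.2 ± 22.2 and 494.6 ± 5.97 FPKM (-0.14). SOX9 was at 67.7 ± 0.977 and 62.7 ± 1.53 FPKM (-0.11), and PLAUR, the urokinase receptor, at 5.89 ± 0.501 and 4.94 ± 0.299 FPKM (-0.21), all with n = 3 and SD. AXIN2 (125.4 and 120.3 FPKM, -0.06) and MYC (85.4 and 87.9 FPKM, 0.04) are classic targets named outside the rule, after their values were seen. LGR5, MMP7, OLFM4 and SMOC2 were below the filter on low values. The list did not pass by camera (adjusted p = 0.128; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.392), while fry's test for change in either direction gave an adjusted p of 0.0172. Its call and size depended on single libraries: the median was -0.047 with an adjusted p of 0.0356 without control siRNA replicate 2, and -0.053 (0.0508) without ITGB4 siRNA replicate 1, but -0.012 (0.64) without control siRNA replicate 1. It also passed without genes that carry any of 4 short words in their 3′ UTR (median -0.064, adjusted p = 0.0107), an alternative chosen after seeing the data.

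The 42 tested components of the Wnt pathway had a median of -0.04, with 30 below 0 and 12 above, and did not pass by camera (adjusted p = 0.189; adjusted p = 0.631 with an estimated correlation). WNT5A, a ligand of the non-canonical branch, was at 24.4 ± 0.558 and 20.96 ± 0.762 FPKM (SD, n = 3 each; log2 fold change -0.21, limma adjusted p = 0.462), the smallest adjusted p of the list.

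Hemidesmosome and laminin genes were described by 14 tested members, of which 7 lay above 0 and 7 below. ITGB4 was the 1 member called changed over all genes tested, and ITGA6, the α6 partner of integrin β4, also passed when adjusted over the list alone (limma adjusted p = 0.0316, 0.514 over all genes). ITGA6 was at 63.3 ± 4.89 FPKM with control siRNA and 52.2 ± 2.26 with ITGB4 siRNA (SD, n = 3 each; log2 fold change -0.27). LAMA5 (-0.11) and LAMB2 (0.07), laminin chains, had overlapping groups. The list, with the siRNA target ITGB4 among its members, had a median of 0.00 and did not pass by camera (adjusted p = 0.196; adjusted p = 0.51 with an estimated correlation).

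Other adhesion and cytoskeleton lists did not pass by camera. The 9 other integrin subunits tested had a median of 0.00 (adjusted p = 0.434), with ITGA2 at 11.5 ± 0.721 and 10.1 ± 0.351 FPKM (log2 fold change -0.17). The 30 focal adhesion and integrin signalling genes had a median of 0.01, while camera's direction was down (adjusted p = 0.97), and RAC1, a small GTPase of actin remodelling, was at 95.7 ± 4.85 and 106.2 ± 4.28 FPKM (0.15). The 18 ezrin, radixin and moesin genes and partners had a median of 0.03 and a mean of 0.00 of the opposite sign (adjusted p = 0.868), with RDX, radixin, at 14.1 ± 1.72 and 10.7 ± 0.719 FPKM (-0.36) and ACTB at 1143 ± 18.3 and 1238 ± 21.6 FPKM (0.11). Epithelial genes had a median of 0.01 over 22 members (adjusted p = 0.943), mesenchymal genes 0.04 over 11 (0.813), and proteases and invasion genes -0.01 over 15 (0.3). With an estimated correlation none of these 6 lists passed either, and limma called 0 of their members over all genes tested, with 2 higher and 7 lower at an unadjusted p under 0.05 (limma-voom 0; a gene in more than 1 list is counted in each).

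Immediate-early and feedback genes of the MAPK pathway fell as a group in camera with the preset correlation, the 1 of 28 lists to pass. Of 27 tested members 21 lay below 0 and 6 above, with a median of -0.06 (adjusted p = 0.0069; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.21, and 0.0557 for change in either direction). Limma called 0 members over all genes tested or adjusted over the list alone (4 lower and 1 higher at an unadjusted p under 0.05; limma-voom 0). EPHA2, an ephrin receptor, was at 65.3 ± 5.62 and 52.3 ± 1.34 FPKM (SD, n = 3 each; log2 fold change -0.31), EGR1, a transcription factor of the immediate-early response, at 34.7 ± 1.87 and 29.5 ± 1.36 FPKM (-0.22), and IER2 at 9.34 ± 0.995 and 10.97 ± 0.799 FPKM (0.21). The list's call was lost without control siRNA replicate 1 (median -0.045, adjusted p = 0.135) and without ITGB4 siRNA replicate 3 (-0.055, 0.0884). It was also lost without genes that carry any of the 4 words (-0.045, 0.0753), chosen after seeing the data. Of the 10 splits of the 6 libraries into 3 and 3, 8 had at least 1 list past the same camera threshold, the real split included. A count of 1 passing list is therefore not particular to the siRNA groups.

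Targets of p53 had a median of -0.05 over 25 tested members, 16 below 0 and 9 above, and camera gave an adjusted p of 0.0581 (0.0359 with limma-voom; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.0941, and 0.0229 for change in either direction). Adjusted over the list alone, 3 members passed. These were AEN, an exonuclease of apoptosis, which carries ATTGGAT and TTGGATA in its 3′ UTR, at 20.3 ± 0.693 and 15.6 ± 0.328 FPKM (log2 fold change -0.36), GDF15, a secreted stress factor, at 10.2 ± 0.859 and 8.11 ± 0.437 FPKM (-0.30), and PERP, a desmosome-associated membrane protein, at 57.4 ± 1.83 and 66.6 ± 2.14 FPKM (0.21). Over all genes tested limma called 0 members (4 lower and 1 higher at an unadjusted p under 0.05), and limma-voom called AEN (adjusted p = 0.0186). The 20 apoptosis regulators lay 10 above and 10 below 0, with a median of 0.00 (adjusted p = 0.426; adjusted p = 0.637 with an estimated correlation; fry adjusted p = 0.525, and 0.0229 for change in either direction). Adjusted over the list alone, MCL1, which protects from apoptosis, at 56.7 ± 1.06 and 47.8 ± 0.34 FPKM (-0.24), was among the members that passed (limma adjusted p = 0.00555). When leaving out 1 library the median of the p53 list ran from -0.076 (adjusted p = 0.0312, without control siRNA replicate 2, which alone passed) to -0.032 (0.134, without ITGB4 siRNA replicate 2), with the highest adjusted p, 0.277, without control siRNA replicate 1. It passed without the filter on low values (-0.057, 0.0205), but with a mean FPKM of at least 5 the median was -0.003 (0.113).

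**Figure D2:**
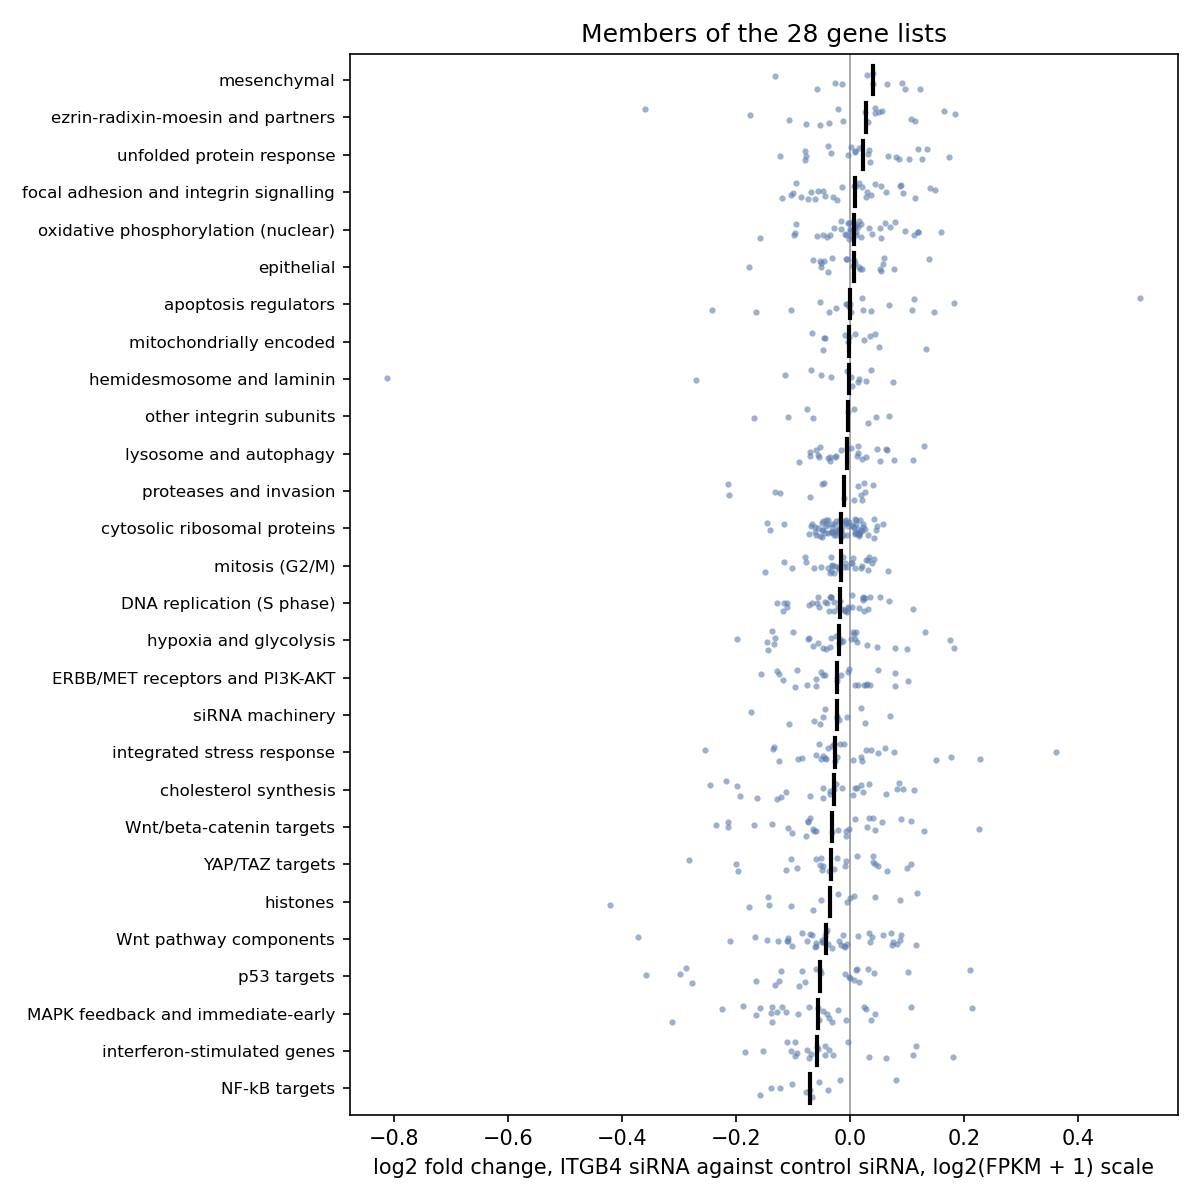
Log2 fold changes (ITGB4 siRNA against control siRNA) of the tested members of the 28 gene lists, 1 point per gene, with a black bar at the median of each list and the lists sorted by median. The medians run from -0.07 (NF-kB targets) to 0.04 (mesenchymal genes), 21 below 0 and 7 above.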

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

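Limma-voom and the fit without the genes with the 4 words were chosen after seeing the data. ITGB4 stayed below 0 in every alternative, from -0.87 to -0.76 when leaving out 1 library (adjusted p 0.0317 to 0.137), and EZR from -0.19 to -0.16 (0.271 to 1). A pseudocount of 0.1, median-of-ratios rescaling and robust moderation each gave 6 genes, all 6 shared with those reported, and TPM gave 7, with 6 shared. Of the comparisons of named genes other than ITGB4 and EZR and of the MAPK and p53 lists, 637 kept direction and side of the threshold, 37 lost the call, 65 gained it, 37 of these in the fit with library weights that did not converge, and 2 turned sign, both CTNNB1.

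With no low-value filter limma called 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold (31956 genes tested, 1356 at an unadjusted p under 0.05), ITGB4 was at -0.81 with an adjusted p of 0.0618, and 4 lists passed. More genes tested raises the adjusted p, and the cause of the rest was not tested. A mean FPKM of at least 5 gave 7 genes, 5 shared with those reported, and 0 at least 2-fold, since AC012531.4 is under this filter. Library weights gave 942 genes, 473 higher, 469 lower and 53 at least 2-fold, and EZR at -0.19 passed (adjusted p = 0.0103), but the weight estimate did not converge and put 27.6 on control siRNA replicate 3 against 0.22 to 1.02 on the others, so this fit is no evidence of more changed genes.

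The replicate block gave 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold (1064 at an unadjusted p under 0.05), ITGB4 at -0.81 (adjusted p = 0.0564) and 2 lists (MAPK and p53). The block takes up residual degrees of freedom. Whether the numbers pair the libraries is not settled. Across genes, deviations from the group mean correlated at 0.173, 0.102 and -0.01 between libraries of the same number, for numbers 1, 2 and 3. Numbers 1 and 2 each matched their own number best, with -0.174 to 0.086 for the other pairs of control siRNA replicates 1 and 2. For number 3 other libraries matched better.

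Leaving out 1 library gave 0 to 7 genes changed, 0 to 4 higher, 0 to 4 lower, 0 to 2 at least 2-fold, and 1 to 7 lists, the 7 without control siRNA replicate 2. Genes changed numbered 7, 6 and 3 without control siRNA replicate 1, 2 or 3 (5, 5 and 1 shared with those reported) and 0 without ITGB4 siRNA replicate 1, 2 or 3, with fewer libraries in the fit. The median of the Wnt/β-catenin targets ran from -0.053 to -0.012 (adjusted p 0.0356 to 0.64) and CTNNB1 from -0.04 to 0.02.

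Limma-voom gave 26 genes, 12 higher, 14 lower and 1 at least 2-fold (SMN1), and 2 lists (MAPK and p53); the cause was not tested. Without the 2151 genes with 1 of the 4 words described under the other observations, limma called 3 genes (AC012531.4, GANAB and ITGB4), 1 lower, and 2 lists passed. One of these was the Wnt/β-catenin targets at a median of -0.064 (adjusted p = 0.0107; 0.0107 to 0.64 over all alternatives), while the MAPK list no longer did (-0.045, 0.0753); the cause was not tested. Camera with an estimated correlation and fry's directional test each passed 0 lists (7 with preset correlation at an unadjusted p under 0.05), while fry's test for change in either direction, another question, passed 4, among them the hemidesmosome list, which holds the siRNA target itself. The planned edgeR and DESeq2 count tests were not run, and limma-voom was run on the recovered reads in their place. Depth limits AC012531.4, at 1 read per control library.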

Other observations

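The word scan, its tests on called genes and the tests of the MAPK list were chosen after the gene calls had been seen.

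Some genes called by limma-voom and not by the reported test are named here after their values were seen. FMR1, a regulator of translation, was at 12.2 ± 1.06 FPKM with control siRNA and 8.06 ± 0.257 with ITGB4 siRNA, and G3BP2, a stress granule protein, at 18.5 ± 1.22 and 25.6 ± 0.657 FPKM (SD, n = 3 each). NOLC1, a nucleolar phosphoprotein, was at 63.0 ± 5.16 and 93.7 ± 3.72 FPKM, and limma also called it with a mean FPKM of at least 5 (adjusted p = 0.036). SMN1, of the spliceosome assembly machinery, was at 6.64 ± 0.895 and 2.33 ± 0.893 FPKM, but it is nearly identical to SMN2, so the assignment of its reads is uncertain. PTPRJ, a receptor phosphatase, was at 11.2 ± 0.101 and 14.04 ± 0.137 FPKM. In the reported test none of these 5 genes passed (limma adjusted p = 0.117, 0.117, 0.109, 0.148 and 0.148). In the 3′ UTR, FMR1 carries ATTGGAT, SMN1 carries ATTGGAT and TTGGATA, G3BP2 carries TCGGAGA and CGGAGAA, and NOLC1 carries TCGGAGA. PTPRJ carries none of these words there.

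The remaining lists did not pass by camera with either correlation. Medians below 0 were found for targets of NF-kB (-0.07 over 11 members, 10 of them below 0, adjusted p = 0.122), interferon-stimulated genes (-0.06 over 22, 0.224), histones (-0.04 over 14, 0.122), YAP/TAZ targets (-0.03 over 24, 0.3), cholesterol synthesis (-0.03 over 27, 0.189), the integrated stress response (-0.03 over 31, 0.99), the siRNA machinery (-0.02 over 13, 0.305), ERBB/MET receptors and PI3K-AKT (-0.02 over 27, 0.381) and hypoxia and glycolysis (-0.02 over 33, 0.374). Cell cycle genes were near 0, with medians of -0.02 for mitosis (34 members, 0.381) and -0.02 for DNA replication (39, 0.381). Cytosolic ribosomal proteins had a median of -0.02 (75, 0.381), lysosome and autophagy genes -0.01 (27, 0.973), mitochondrially encoded genes 0.00 (13, 0.935), nuclear oxidative phosphorylation genes 0.01 (41, 0.426) and the unfolded protein response 0.02 (22, 0.224). HSPA5, the main chaperone of the endoplasmic reticulum, was at 137.9 ± 2.47 and 149.8 ± 1.19 FPKM (SD, n = 3 each; log2 fold change 0.12, limma adjusted p = 0.676). Of the intestinal differentiation genes, CDX2 (22.1 and 20.4 FPKM) and HNF4A (1.595 and 1.602 FPKM) alone reached the filter.

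Genes lower with ITGB4 siRNA shared a word in their 3′ UTR. ATTGGAT marked lower values most strongly of 16178 words (1077 genes, median log2 fold change -0.029 against -0.002, Bonferroni-adjusted p = 1.04e-08). Of the 13 lower genes called by limma-voom other than ITGB4, 12 carried it or TTGGATA, against 17.3% of other genes (one-sided Fisher's exact p = 7.94e-09). The exception, SLC36A1, carried neither word anywhere in its longest transcript. SETD7 carried both words, and TCGGAGA as well, but limma-voom called it higher. A scan that left the called genes out again put ATTGGAT first (adjusted p = 1.79e-07), with 12 of 13 called genes as carriers of it or TTGGATA (Fisher's exact p = 7.99e-09). Gene sets matched for UTR length held at most 9 carriers in 10000 draws, which argues against UTR length as the cause. The scan and the gene calls used the same 6 libraries, and Fisher's test treats genes that vary together as independent. These p-values therefore cannot tell an effect of the siRNA from a structure of the samples. An siRNA can lower transcripts that match its bases 2 to 8, so such matches of the ITGB4 siRNA are a candidate explanation; ITGB4 itself holds 1 ATTGGAT in exon 6 (GRCh38 chromosome 17, 75728412 to 75728418), but so do 26.5% of transcripts of similar length. Across libraries the genes with both words differed by -0.053 (exact permutation p = 0.4), or by -0.039 (p = 0.1, the smallest possible) with UTR length and GC content regressed out, a version chosen after the former was seen. TTGGATA was also the top word of other splits. That of control siRNA replicate 1 with ITGB4 siRNA replicates 1 and 2 gave an absolute z of 6.64. It had 23 words past the threshold against 13 in the real split, which points to a structure of the samples. That of control siRNA replicates 1 and 2 with ITGB4 siRNA replicate 3 gave 5.21. Each side of both splits still held mostly libraries of a single group, so part of the siRNA contrast remained in them. These splits therefore cannot tell whether the shift follows the siRNA groups alone. With UTR length and GC content regressed out, the score was 0.019 to 0.02 in control libraries and -0.023 to -0.014 in ITGB4 siRNA libraries. The words were picked on these same groups. A response of these genes to less ITGB4 also stays open and untested.

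Genes higher with ITGB4 siRNA shared TCGGAGA (230 genes, median log2 fold change 0.035 against -0.006, Bonferroni-adjusted p = 2.22e-08), and 8 of the 12 higher genes called by limma-voom carried it or CGGAGAA, against 4.1% of other genes (one-sided Fisher's exact p = 3.37e-09). These words were picked with the called genes in the scan; with those left out, GGAGAAA and TCGGAGA came first (adjusted p = 1.01e-06 and 1.18e-06), and either was carried by 10 of the 12 against 23.6% of others (Fisher's exact p = 2.22e-05). Lowering by the control siRNA in the control libraries is a candidate explanation: TCGGAGA matches bases 2 to 8 of the strand that begins with UUCUCCGA in a widely used control duplex, and the match to its other strand, TGTCACG, also marked higher genes (n = 327 genes, one-sided rank test across genes, p = 0.000406, rank 21), although the overlapping GTCACGC had been seen among the top words before that test. Across libraries the genes with both TCGGAGA and CGGAGAA differed by 0.075 (exact permutation p = 0.1, the smallest possible). These words were picked on these same groups, so that p is not independent evidence of a shift. The Fisher's exact tests of the higher genes have the same limit, and they also treat genes that vary together as independent. GANAB and PTPRJ carried neither word anywhere in their longest transcript, the labels do not name the control siRNA, and a response to less ITGB4 stays open and untested.

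The MAPK list had a median of -0.056, and 18 of its 27 members carry TATTTAT, an AU-rich word that also marked lower genes. Against 10000 random lists of genes with that word its median lay at percentile 1.65. It was below their 2.5% bound of -0.053 by less than the bootstrap standard error of the median, 0.028, a margin added after the value was seen. Every member of those random lists carried the word, against 18 of 27 here. Genes with the word had a median of -0.018 and genes without it 0.002, so the bound may be lower than for lists with the same share of carriers. Such lists were not drawn. A general shift of AU-rich transcripts therefore cannot be told apart from a change of this list. Against that shift as the whole cause, the 9 members without the word had a median of -0.072, the 18 with it -0.055, and all 3666 tested genes with it -0.018, but 9 members are too few to exclude it. Its 8 members with ATTGGAT or TTGGATA had a median of -0.137, and the 19 without them -0.041, which keeps the sign but lies inside the bound of -0.042 for random lists, so a contribution of the siRNA words cannot be told apart either. A lower MAPK response with less ITGB4 stays open and untested.

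With 3 against 3 libraries there are 10 splits, so no share under 0.1 can be reached. The real split gave 6 genes and the highest of the others 1 (1 split as large, the real one included), 1 gene at least 2-fold against 1 (2 splits), 26 genes by limma-voom against 1 (1 split), 1 list against 6 (8 splits), and a largest word score of 7.10 against 6.64 (1 split). The split of control siRNA replicates 1 and 3 with ITGB4 siRNA replicate 1 gave the 6 lists, which points to a structure of the samples. EZR carried neither ATTGGAT nor TTGGATA in its 3′ UTR, and its log2 fold change of -0.18 lay at percentile 3.1 of the 1933 genes with the shorter TTGGAT alone and at percentile 3.1 of all genes in the scan, so this comparison adds nothing to its overall rank.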
